A study of Mus musculus with 4 samples.

How the data were processed

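RNA from mouse embryonic stem (ES) cells was measured on 4 expression arrays, 2 from wildtype cells and 2 from SOCS3-null cells, with the group and the replicate number of each array taken from the submitters' labels. The labels name total RNA from embryonic stem cells and give no culture condition, clone or passage. Nothing in them says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

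The deposited values are intensity values on a linear scale, with 45101 probe sets on each array. The summarisation and normalization that the authors used are not given in the sources used here. The values themselves were all above 0, and the medians of log2(intensity + 16) differed by at most 0.01 between arrays, so they were treated as already normalized between arrays and were not normalized again. Array medians were 16.0 and 16.0 in wildtype and 15.8 and 15.8 in SOCS3-null, and the 75th percentiles lay between 115 and 120. A normalization that makes the arrays' distributions nearly equal removes any change in total RNA per cell. No detection calls were used here, so an intensity near the array median is read as dim and not as absent. The number of arrays limits the precision.

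Tests were run with limma 3.58.1 in R 4.3.3 on log2(intensity + 16), a pseudocount that understates the change of dim genes. The 64 control probe sets were left out, and 27022 probe sets whose mean over the 4 arrays reached the 40th percentile were tested. Gene symbols came from a platform annotation. Of the probe sets that were not controls, 34945 had 1 symbol, 932 had several and 9160 had none; probe sets with several symbols or none were not named. The annotation's gene IDs found 34741 of the named probe sets in a RefSeq gene table of assembly GRCm38.p6, with 0 symbols changed. For results per gene, the probe set with the highest mean over all 4 arrays stood for its gene, which gave 12732 genes, 6007 of them with more than 1 probe set tested. Each row was fitted with lmFit and eBayes with genotype as the only term, and a row was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A change is the SOCS3-null mean minus the wildtype mean on the log2 scale, with its standard error (SE); intensities are given as mean ± SD with n = 2 arrays.

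There were 22 gene lists with 460 entries, of which 392 were tested, written with the design and the named-gene rule before the data were examined. Each list was tested with camera at a preset correlation between genes of 0.01, which compares the list with all other genes, with adjustment over the 22 lists. Camera with an estimated correlation and fry were run beside it. The estimated correlation rests on 2 residual degrees of freedom, so a list that it does not call is not thereby shown to be unshifted. Some genes stand in more than 1 list. Named genes were Socs3 and Ptpn11, the 12 largest increases and 12 largest decreases among called genes with both SOCS3-null arrays on the same side of both wildtype arrays (clone names left out), the 4 members of each list with the smallest p, and the fixed genes Pou5f1, Nanog, Sox2, Klf4, Zfp42, Gata4, Gata6, Sox17, Dab2 and Stat3. Members named beyond this rule, mostly because a count was 5 or fewer, were chosen after their values were seen and are marked so.

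The procedure was tested on 10 simulated data sets per number of changed genes for the comparison of SOCS3-null with wildtype. They were built from the means of the 12732 genes and their residual variances after moderation by eBayes. With 200 changed genes, 85.9% of those changed by 1 on the log2 scale were found, 98.3% of those changed by 2 and 99.4% of those changed by 3, and 6.02% of calls were false. With 2546 changed genes, 97.6% of those changed by 1 were found, and 3.95% of calls were false. A list of 30 genes shifted by 1 had a camera p under 0.05 in 10 of 10 data sets. Simulated noise was normal and independent between genes, which real arrays need not be.

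Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, eBayes with a trend and with a robust trend, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. Chromosome assignments and the order of neighbouring genes came from the GRCm38.p6 table. Figures were drawn with matplotlib 3.10.9.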

Results

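Expression was compared between mouse ES cells that lack SOCS3, an inhibitor of cytokine signalling through JAK kinases and STAT3, and wildtype ES cells. The keywords in the labels name endoderm, SHP2, leukemia inhibitory factor (LIF, the cytokine that holds mouse ES cells undifferentiated) and ERK1/2. The data were 4 arrays, 2 per genotype. The correlation of log2 values across the probe sets tested was 0.995 between the wildtype arrays, 0.988 between the SOCS3-null arrays and 0.948 to 0.957 across genotypes. Genes are not independent replicates in these correlations.

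The targeted transcript was examined first. The intensity of Socs3 on its brightest probe set was 3024 and 1884 on the wildtype arrays and 19.3 and 12.9 on the SOCS3-null arrays, or 2454 ± 807 against 16.1 ± 4.55 (SD, n = 2). Its log2 change was -6.23 (SE 0.28), with a limma adjusted p of 0.00847 over all probe sets tested. The other probe sets of Socs3 changed by -4.87 and -4.15, with adjusted p of 0.00819 and 0.00792. The labels do not say which part of the gene was removed, and a probe set outside that part would check nothing. With any 1 array left out the change was -5.89 to -6.57. Both SOCS3-null intensities lay near the array medians, so the size of the change depends on the pseudocount.

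The comparison of genotypes asks which transcripts depend on SOCS3. Of 30 tested genes of the primitive and extraembryonic endoderm 25 rose in SOCS3-null cells, as did 14 of 20 genes of basement membrane and matrix. Of 12 formative epiblast genes 7 fell and 1 rose, and 4 of 10 neuroectoderm genes fell. Among 26 pluripotency genes 10 fell and 3 rose, while Pou5f1 did not pass the test in either direction. With an estimated correlation between genes camera called 0 of the 22 lists. That form rests on 2 residual degrees of freedom, and its unadjusted camera p for the endoderm list was 0.0246. The neuroectoderm and G2-M lists, with negative estimated correlations of -0.087 and -0.033, had the same adjusted p of 0.449 as the endoderm list. The 0 calls therefore do not show that correlation between genes accounts for the shifts. Of 12732 genes tested, 2888 were called, or 22.7%, of which 1672 were higher and 1216 lower in SOCS3-null cells. Of the called genes, 1183 changed by at least 1 on the log2 scale, 750 up and 433 down, and 263 changed by at least 2, 182 up and 81 down. By probe set, 4283 of 27022 were called, 2310 higher and 1973 lower. Without the filter on dim probe sets 1631 genes were called. With any 1 array left out limma called 0 genes, while 2928 to 4733 genes had an unadjusted p under 0.05.

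Among the largest increases was that of Srgn, which encodes a granule proteoglycan, from 27.3 ± 11.9 to 7099 ± 360 (SD, n = 2), a log2 change of 7.39 (SE 0.22, adjusted p = 0.0043). Cubn and Amn, whose products form an endocytic receptor of the visceral endoderm, rose by 6.95 and 4.72. Clu, a secreted chaperone, rose by 6.83 from 99.3 ± 9.74 to 13206 ± 2060 (SD, n = 2). The transcription factors of the primitive endoderm Gata6, Sox17 and Gata4 rose by 5.25, 5.02 and 4.63, with SE of 0.27, 0.10 and 0.20. Sox17 went from 4.29 ± 0.299 to 645 ± 56.5 and Gata4 from 10.3 ± 3.20 to 640 ± 146 (SD, n = 2). The growth factor receptor Pdgfra rose by 5.23, the endocytic adaptor Dab2 by 4.68 and Dram1, a lysosomal membrane protein, by 4.83. The mean wildtype intensities of Cubn, Gata4, Gata6, Sox17 and Dram1 lay below the array medians, so their log2 changes depend on the pseudocount. Other increases moved with the settings too: over the alternatives Srgn ran from 6.30 to 8.04, Pdgfra from 3.63 to 5.97, Amn from 3.54 to 5.51 and Dab2 from 3.38 to 5.10. The pseudocount also sets the order of increases: with a pseudocount of 1 Cubn (8.08) came before Srgn (8.04).

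**Figure D1:**
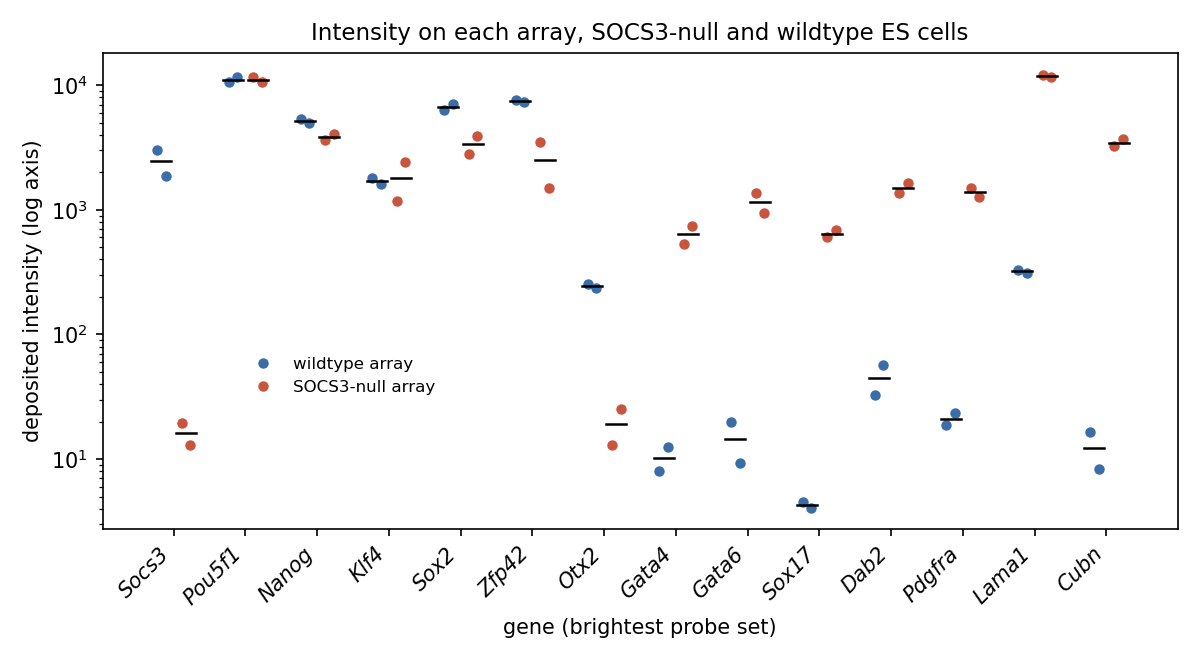
Deposited intensity (log axis) of 14 genes on each array, with wildtype arrays in blue, SOCS3-null arrays in red and the mean of each group as a black line. Socs3 lies at 3024 and 1884 on the wildtype arrays and at 19.3 and 12.9 on the SOCS3-null arrays, Pou5f1 overlaps between genotypes, and Gata4, Gata6, Sox17, Dab2, Pdgfra, Lama1 and Cubn lie higher on both SOCS3-null arrays than on both wildtype arrays.

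The list of primitive and extraembryonic endoderm genes had 30 members tested, of which 25 rose, 0 fell and 5 did not pass the test, and 25 rose when adjusted over the list alone. Its median log2 change was 3.30, with a camera adjusted p of 3.04e-16, against an adjusted p of 0.449 with an estimated correlation. Members that did not pass were Fst, Thbd, Hnf4a, Apoa1 and Ttr, chosen after their values were seen, with changes from -0.05 to 0.45. Afp, Apob and Ihh of this list lay below the filter and were not tested. Sox17 and Gata4, with wildtype log2 means of 4.34 and 4.71, reached the filter floor of 4.72 only through the SOCS3-null arrays. The count of 25 thus belongs to the members that passed the filter. The list of basement membrane and matrix genes had 20 members, of which 14 rose and 1 fell, or 16 and 1 when adjusted over the list alone. Its median was 1.70, with a camera adjusted p of 4.31e-07 and an adjusted p of 0.449 with an estimated correlation. Col4a1, a type IV collagen chain, rose by 5.22 from 311 ± 26.4 to 12161 ± 553, and the laminin chains Lama1 and Lamc1 rose by 5.15 and 3.46. The collagen chaperone Serpinh1 rose by 3.63. Col18a1, chosen after its value was seen, changed by -1.85. The 2 lists share 7 members, all of which rose. Of the 13 basement membrane genes outside the endoderm list 7 rose and 1 fell, with a median of 0.62.

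Markers of other cell types changed less. The median changes beside the 3.30 of the endoderm list were 0.21 for mesoderm and primitive streak, 0.30 for trophoblast, 0.12 for fibroblast and feeder cells, 0.54 for blood and endothelial cells and -0.48 for neuroectoderm. In a test chosen after the values were seen, the endoderm median exceeded that of the 56 genes of these lists together by 3.16 (bootstrap 95% interval over genes 2.22 to 4.41). Of 11 mesoderm genes 2 rose, 0 fell and 9 did not pass (camera adjusted p = 0.149). They were Snai1, a repressor of epithelial genes, with a change of 2.19, and Eomes with 0.94. Of 9 trophoblast genes Eomes rose and Tfap2c fell (-1.11), and 7 did not pass (adjusted p = 0.381). Of 23 fibroblast genes 2 rose, 0 fell and 21 did not pass (adjusted p = 0.36): the matricellular gene Ccn1 rose by 2.19 and S100a6 by 1.04. With an array left out the fibroblast median ran from -0.17 to 0.48, and the list passed without wildtype replicate 2 (0.44, adjusted p = 0.0145; range over its alternatives 0.0145 to 0.978). Of 6 blood and endothelial genes 3 rose and 0 fell (adjusted p = 0.0449, and 0.449 with an estimated correlation): Cdh5 went from 5.89 ± 1.01 to 27.6 ± 0.0254, Tek rose by 0.56 and the macrophage gene Cd68 by 1.13, from 95.6 ± 7.43 to 230 ± 49.8 (SD, n = 2). This list lost its call without wildtype replicate 1 (0.0638), wildtype replicate 2 (0.0577) or SOCS3-null replicate 1 (0.0969), with a pseudocount of 64 (0.0656), and without the filter (0.144), where the median was 0.00, so its 0.54 belongs to the members that passed the filter. Adjusted over the list alone, 1 mesoderm gene, 1 fibroblast gene and 3 blood and endothelial genes rose, and 3 trophoblast genes rose and 1 fell.

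Pluripotency genes did not move together. Of 26 members of the naive and core pluripotency list, 10 fell, 3 rose and 13 did not pass, or 12 and 4 when adjusted over the list alone. The median was -0.39, with a camera adjusted p of 0.0281 and an adjusted p of 0.449 with an estimated correlation; without wildtype replicate 2 the adjusted p was 0.0864. Pou5f1 was at 11100 ± 814 in wildtype and 11045 ± 737 in SOCS3-null cells (SD, n = 2), a log2 change of -0.01 (SE 0.10, adjusted p = 0.975). Klf4 differed by -0.02 (SE 0.38, adjusted p = 0.983), with 1178 and 2411 on the SOCS3-null arrays and a change of -0.53 to 0.50 over the alternatives, so its direction stays open. Nanog differed by -0.42 (adjusted p = 0.0565) and Zfp42 by -1.70 (SE 0.44, adjusted p = 0.0691). Sox2 changed by -1.01, from 6735 ± 514 to 3382 ± 789 (SD, n = 2), with a limma adjusted p of 0.0385 over genes. Its probe set did not pass over all probe sets (0.0515). Sox2 passed in 8 of 14 alternatives, where Lama1 passed in 10. Tcl1, Prdm14 and Nr0b1 changed by -1.83, -1.51 and -1.36. The largest fall of the list was that of Dppa3 by -3.10 (limma adjusted p = 0.0157), chosen after its value was seen. The members that rose were Tbx3 by 1.78, Tfcp2l1 by 1.23 and Klf5 by 0.92, all transcription factors of the naive state.

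Of 12 genes of the formative and primed epiblast 7 fell, 1 rose and 4 did not pass, with the same counts when adjusted over the list alone, and the median was -0.94 (camera adjusted p = 0.00513, and 0.449 with an estimated correlation). Lef1, a mediator of Wnt signalling, changed by -3.01, the head and epiblast factor Otx2 by -2.92, the DNA methyltransferase Dnmt3a by -1.91 and the TGF-beta family ligand Nodal by -1.64. Dnmt3l, chosen after its value was seen, rose by 0.48. Of 10 neuroectoderm genes 4 fell and 0 rose, or 5 and 0 over the list alone, with a camera adjusted p of 0.0162 and one of 0.449 with an estimated correlation. Neurod1 changed by -1.95, Tubb3 by -1.79, Gbx2 by -1.03 and the dim Map2 by -0.98 (-1.79 to -0.41 over the alternatives). The neuroectoderm median of -0.48 was -0.08 without the filter (adjusted p = 0.00792) and -1.03 with the filter at the 60th percentile (0.0299; range over its alternatives 0.00597 to 0.449). Among the largest decreases after Socs3 were Trh, the precursor of thyrotropin-releasing hormone, with -5.47, from 2058 ± 237 to 33.3 ± 23.0 (SD, n = 2), Pla2g1b, a secreted phospholipase, with -4.86, and the Nodal antagonist Lefty1 with -4.47 (SE 0.54). The piRNA pathway gene Tdrd12 changed by -3.95, and the neuronal genes Ina, Crmp1 and Gng3 by -3.83, -3.79 and -3.11. For Enpp3, Ldhb, Slc27a2 and Nphs1 the changes were -3.65, -3.46, -3.40 and -3.18. Decreases to a dim level also depend on the pseudocount: at 1 and 64 the changes were -4.34 and -1.74 for Lef1, -3.69 and -1.90 for Otx2, -4.83 and -2.53 for Crmp1, and -4.42 and -2.19 for Slc27a2.

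**Figure D2:**
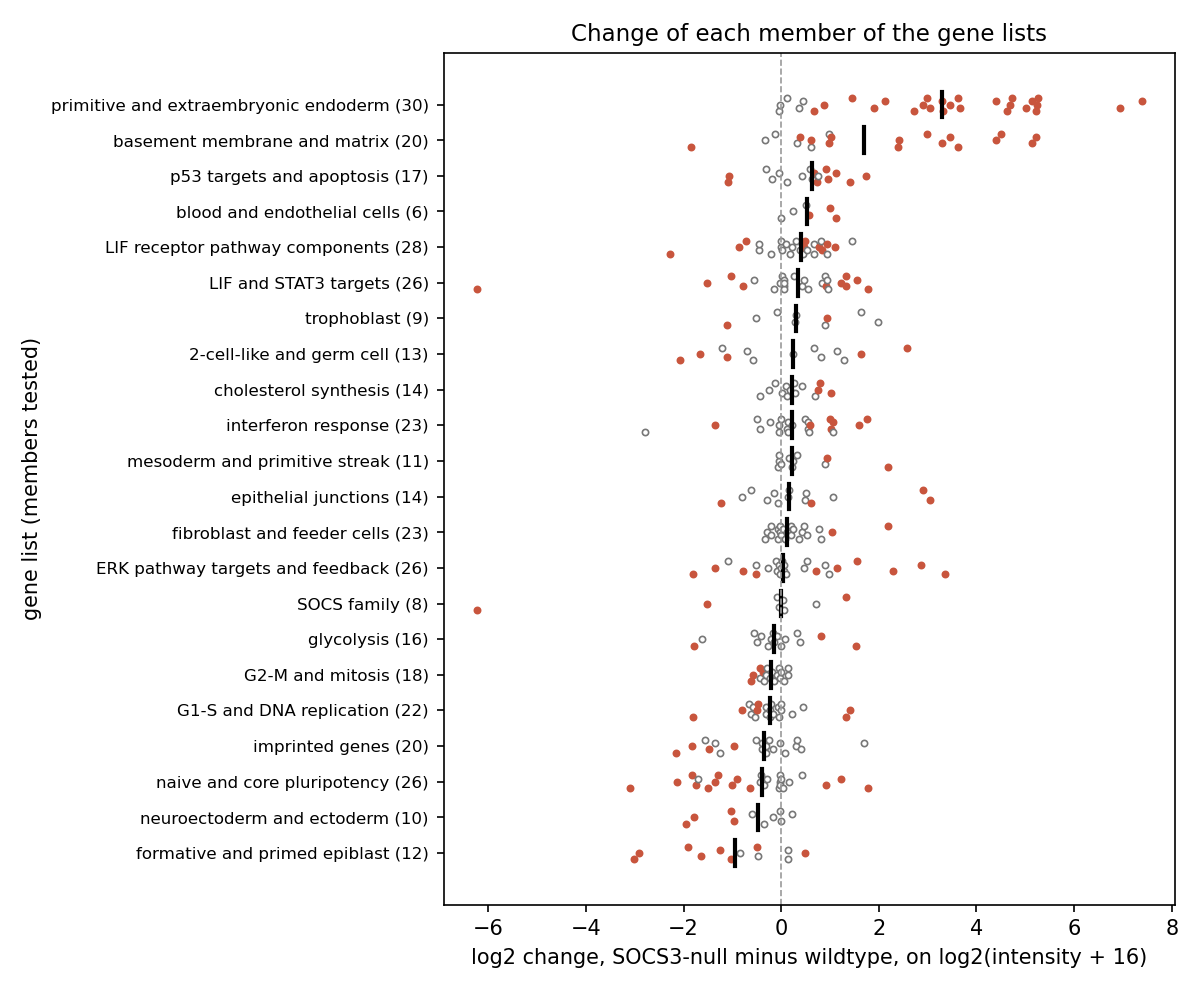
Log2 change of each tested member of the 22 gene lists, SOCS3-null minus wildtype, with called genes filled, other genes open and the list median as a black bar; list sizes are in parentheses. Endoderm genes have a median of 3.30 and formative epiblast genes one of -0.94.

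SOCS3 limits signalling from the LIF receptor, and the transcripts of that pathway moved both ways. Of 26 LIF and STAT3 target genes 6 rose, 4 fell and 16 did not pass, or 10 and 4 over the list alone (median 0.34, camera adjusted p = 0.171). Gadd45g, a stress response gene, rose by 1.77 with Klf5 and Tfcp2l1. Those that fell were Socs3 itself, Socs2 (-1.53), Gbx2, and Myc (-0.79), the last chosen after its value was seen. The counts and the camera test of this list thus include the targeted gene, with its change of -6.23. The test was not run without Socs3, which pulls the list down. Stat3 differed by 0.42 (adjusted p = 0.0671) and Ptpn11, which encodes SHP2, by 0.45 (SE 0.10, adjusted p = 0.0547). Of 28 LIF receptor pathway components 6 rose, 3 fell and 19 did not pass, or 11 and 4 over the list alone (median 0.40, camera adjusted p = 0.0449, and 0.512 with an estimated correlation). Without wildtype replicate 1 the adjusted p was 0.0922, and without SOCS3-null replicate 1 it was 0.0705. Lifr, the receptor subunit for LIF, rose by 1.11 from 655 ± 23.4 to 1429 ± 27.6 (SD, n = 2) and Jak2 by 0.83. Stat4 changed by -2.27, Sos1 by -0.72 and Ptpn6, chosen after its value was seen, by -0.87. In the SOCS family, with 8 members, Socs1, dim in wildtype, rose by 1.32 (0.63 to 2.16 over the alternatives) and Socs3 and Socs2 fell. Socs5 differed by 0.71 (limma adjusted p = 0.0504). Over the list alone 2 rose and 2 fell, and the list's camera adjusted p was 0.663. That test, too, includes the targeted Socs3.

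Targets and feedback genes of the ERK pathway also split. Of 26 members 6 rose, 4 fell and 16 did not pass, or 6 and 5 over the list alone, with a median of 0.03 and a camera adjusted p of 0.593. Phlda1 rose by 3.36 from 102 ± 1.40 to 1190 ± 37.3 (SD, n = 2) and Plaur, the urokinase receptor, by 2.87. Dusp4 and Dusp6, phosphatases that act on ERK, rose by 2.29 and 1.14 and were chosen after their values were seen. Ccnd1 (-1.81) and Etv5 (-1.37) fell, as did Myc and Spred1, both chosen after their values were seen.

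Among the remaining lists, 7 of 17 p53 and apoptosis genes rose and 2 fell, or 10 and 3 over the list alone (median 0.63, camera adjusted p = 0.0449, and 0.463 with an estimated correlation). That call was lost without wildtype replicate 1 (0.0709), wildtype replicate 2 (0.0577) or SOCS3-null replicate 2 (0.0588). Phlda3 rose by 1.73, the cell cycle inhibitor Cdkn1a by 1.41 and the survival gene Bcl2l1 by 1.11. Bid changed by -1.09, and Gadd45a, chosen after its value was seen, by -1.07. Of 18 genes of G2-M and mitosis 4 fell and 0 rose, with the same counts over the list alone: Mad2l1 by -0.62, Kif11 by -0.58, Bub1 by -0.43 and Bub1b by -0.37 (adjusted p = 0.0239 for the list, 0.449 with an estimated correlation and 0.0574 with the filter at the 60th percentile). Bub1 and Bub1b passed in 7 and 5 of 14 alternatives, where Lama1 passed in 10. Their changes were -0.14 and -0.13 as the mean of their probe sets. Each has a dimmer probe set (wildtype means 53.6 and 22.1) that was not called and lay higher in SOCS3-null cells (0.15 and 0.40). Bub1b has a further probe set, bright in wildtype (1467), that changed by -0.42 (limma adjusted p = 0.0402 over all probe sets). Of 20 imprinted genes 4 fell and 0 rose, also over the list alone: Peg3 by -2.15, Phlda2 by -1.82, Nnat by -1.48 and Impact by -0.96 (adjusted p = 0.0449, and 0.449 with an estimated correlation). The imprinted list was called in 8 of 15 alternatives, and not without wildtype replicate 2 (0.0762) or SOCS3-null replicate 1 (0.0602).

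The other lists did not pass camera. Of 22 genes of G1-S and DNA replication 2 rose and 4 fell (adjusted p = 0.0733, and 0.0296 without SOCS3-null replicate 1). Cdkn1a and Ccnd3 were the 2, and Ccnd1, E2f1, Mcm2 and Mcm4 the 4, with Ccnd3 and Mcm4 chosen after their values were seen. Of 23 interferon response genes 6 rose and 1 fell (adjusted p = 0.114): the antigen presentation genes Tap1, H2-D1 and Psmb9 rose by 1.76, 1.60 and 1.02, and the transcription factor Irf1 fell (-1.35). Of 14 epithelial genes the keratins Krt8 and Krt18 rose by 3.05 and 2.91, Tjp1 rose by 0.62 and Epcam fell with -1.22 (adjusted p = 0.69). Of 14 cholesterol synthesis genes Srebf2, Mvd and Cyp51 rose by 1.03, 0.80 and 0.75 (adjusted p = 0.141). In the glycolysis list of 16, Vegfa, a growth factor, and Hk1 rose by 1.53 and 0.81, and Bnip3, a mitophagy gene, fell with -1.79 (adjusted p = 0.427). Of 13 2-cell and germ cell genes Rhox5 rose by 2.58 and Usp17la, dim in wildtype, by 1.63 (0.86 to 2.33 over the alternatives). Prdm1, Tfap2c and Stra8, the last chosen after its value was seen, fell (camera adjusted p = 0.969 for the list). Over the list alone the counts of genes that rose and fell were 3 and 7 for G1-S, 8 and 1 for interferon, 3 and 3 for epithelial junctions, 3 and 0 for cholesterol, 2 and 1 for glycolysis and 3 and 3 for the germ cell list. Fry asks whether the genes of a list move, on balance, in the same direction, without comparing them with other genes. Its adjusted p was 0.0204 for the ERK and the mesoderm list, 0.0418 for the germ cell, 0.0431 for the interferon and 0.0458 for the cholesterol list, all up, where camera did not pass, and 0.0546 for the LIF receptor pathway components, where camera did. For the other lists both tests fell on the same side of 0.05. Of the 55 named genes with more than 1 probe set tested, 19 had called and uncalled probe sets, and Pdk1 had called probe sets in opposite directions. As with Sox2, the calls of S100a6, Eomes and Socs1 over genes were not made over all probe sets (adjusted p of 0.0530, 0.0600 and 0.0544).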

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

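The alternatives with rows without ties, with genes steady in the SOCS3-null arrays and with crossed replicate numbers were chosen after seeing the data. No result changed its direction while passing the test on either side. The number of genes called, 2888, stayed between 2586 and 3195 with pseudocounts of 1 and 64, quantile normalization, median centring, a filter at the 60th percentile, both eBayes trends and the mean of probe sets, and was 3094 without the 6.38% of probe sets whose 2 arrays of a group held exactly equal values and 3078 without genes that differed by 1 or more between the SOCS3-null arrays. Without a filter it was 1631 (1733 of 45037 probe sets), of which 1525 were shared with the 2888. With any 1 array left out limma called 0 genes and 0 probe sets, at unadjusted p under 0.05 in 2928 to 4733 genes and 5715 to 8552 probe sets; these fits leave 1 array in an arm, which is assumed to vary like the other group. They also leave 1 residual degree of freedom, which raises p even where a change hardly moves. The change of Socs3 with any 1 array left out was -6.57 to -5.89. In the other alternatives its limma adjusted p was 0.000407 to 0.0326. Whether the loss of arrays accounts for all of that drop was not tested, nor was the cause of the drop without a filter. All 91 other named genes that were called kept their sign in every alternative, and 0 of them passed the threshold in all. That 0 follows from the fits with an array left out, which leave 1 residual degree of freedom: even Lama1 passed in 10 of 14. Gene lists called numbered 10, and 6 with a pseudocount of 64, 5 with the filter at the 60th percentile, 7 to 9 with an array left out, and 0 with an estimated correlation, where medians stay at 3.30 for endoderm, -0.94 for formative epiblast and -0.39 for pluripotency genes and the adjusted p is 0.449 for each. The pluripotency list ranged from -0.45 to -0.32 with an array left out and lost its call without wildtype replicate 2 (-0.32, adjusted p = 0.0864; range over its alternatives 0.00597 to 0.449); the cause was not tested. Calls held in 7 of 14 alternatives for blood and endothelial, 8 of 15 for imprinted and p53, 9 of 15 for LIF receptor pathway and 13 of 15 for G2-M genes. The replicate numbers were not taken to pair the arrays: with 2 pairs, deviations of same-numbered arrays correlated at -0.12. With the replicate number as a block 1914 genes and 1993 probe sets were called, and 7 lists, without blood and endothelial (0.0566), LIF receptor pathway (0.0605) and p53 genes (0.0515). With the numbers crossed as a block 2817 genes and 3845 probe sets were called. The other splits of the 4 arrays into pairs called 0 genes, against 2888. At most 93 genes had an unadjusted limma p under 0.05 there, against 4905 in the real split. Each of these splits mixes the genotypes within its pairs, so the genotype difference enters the spread and few calls were to be foreseen. With 3 splits in all the share cannot fall under 0.05, and the real split was the only 1 with as many genes.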

Other observations

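The genes in the first 2 paragraphs, and the tests on the endoderm list, on the RNA quality and endoderm share behind differences between the SOCS3-null arrays, and on chance and a few strong genes for chromosome 8, were chosen after the results were seen. Among the next-largest increases at a pseudocount of 16, P4ha2, a collagen prolyl hydroxylase, rose by 4.50 (SE 0.21), Col4a2 by 4.39, and the chaperone Lrpap1, which escorts receptors of the LDL receptor family, by 3.70 from 598 ± 17.5 to 7947 ± 148 (SD, n = 2). Podxl, a sialomucin of the apical surface, rose by 3.84, and the peptidase Htra1 by 3.77. Klb, a co-receptor for endocrine FGFs, rose by 4.28 and Pth1r, the parathyroid hormone receptor of parietal endoderm, by 3.58. Among the next-largest decreases were Dppa3 of the pluripotency list (-3.10), Zic5 (-2.82), Foxp1 (-2.97), the polycomb gene Phc1 (-2.50, from 6838 ± 77.1 to 1219 ± 354) and Igfbp2 (-2.49). Adjusted p of all of these were 0.0195 or less.

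Transferrin receptor mRNA was lower (Tfrc, -1.01, SE 0.08, adjusted p = 0.00867). The control probe sets for the same mRNA, which no test of the report used, differed by -1.70, -1.94 and -1.84 for the 3', 5' and middle part. Erdr1 rose by 2.83 from 1183 ± 281 to 8406 ± 1007 (SD, n = 2). The neighbours of Socs3 in the gene table did not move alike: Usp36 changed by -0.92, Syngr2 rose by 0.92 and Birc5 differed by -0.35 (adjusted p = 0.0717).

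A lower share of stem cells that raises the markers of every other cell type alike is argued against as the source of the endoderm rise. The endoderm median exceeded that of 56 genes of other lineages and cell types by 3.16 (bootstrap 95% interval over genes 2.22 to 4.41). Stem cells replaced by endoderm cells alone would also give such a gap, so the test cannot exclude a lower share of stem cells. Feeder or fibroblast cells are argued against as that source by the fibroblast median of 0.12 (-0.03 to 0.42), and -0.17 to 0.48 with an array left out. That interval treats genes as independent, while the estimated correlation between these genes was 0.75, so it may be too narrow. A smaller change in the share of such cells stays open, and Vim (4472 ± 1485) and Col1a2 (1057 ± 330) are bright in SOCS3-null cells as in wildtype. A loss of stem cells at 1 rate would lower the 26 pluripotency genes alike only if the other cells expressed none of them. Of the 26, 19 had a 95% interval that excluded the list median, but these intervals are unadjusted and rest on 2 arrays per group. The pseudocount also shrinks the changes of dim genes, so this count does not exclude such a loss. A candidate explanation, as a hypothesis, is that part of the SOCS3-null cells took on a primitive endoderm state, or that all did in part; the arrays measure pools and cannot separate these, nor SOCS3 loss from other differences between the lines. Of the 3 splits of the arrays, 1 called as many genes as the real split, namely the real split itself, and the highest other called 0. These are too few splits to judge chance, and the others mix the genotypes within their pairs, which by itself lowers their calls.

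Over 417 genes of chromosome 8 with a mean intensity of at least 100 the median change was 0.22, or 0.24 above other chromosomes, with 67.6% of genes up, and 0.30 and 0.11 on the SOCS3-null arrays. The permutation p adjusted over 20 chromosomes was 2.0e-04, the smallest 100000 permutations can give here, which argues against random scatter but treats genes as independent; chromosome 13 reached the same adjusted p with a median of -0.18. Movement of up to 1 in 10 genes is argued against by the share of all 417 genes above the median elsewhere, 69.1% (bootstrap over blocks of neighbours 59.9 to 77.5), where it would give at most 55%. The 25th percentile was 0.20 above that of other chromosomes and 7 of 10 blocks of 40 neighbouring genes had a median above 0, so an extra copy of the chromosome in part of the cells stays a candidate explanation, as a hypothesis without a DNA measurement. On chromosome 13 the 25th and 75th percentiles differed by -0.08 and -0.16 from other chromosomes, the SOCS3-null arrays by -0.16 and -0.14 from wildtype, and 7 of 7 blocks lay below 0, so a lower copy number there stays as open.

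Among 7208 autosomal and X-linked genes with a mean intensity of at least 100, the 2 SOCS3-null arrays differed by at least 1.5 on the log2 scale at 34 genes, against 0 genes between the wildtype arrays, and 1 of the 34 was called. Rpgrip1 was at 5393 and 6030 in wildtype and at 4216 and 36.1 in SOCS3-null cells, and its neighbour Supt16 at 615 and 651 and then 487 and 2861. Y-linked genes were not in that set. Of these, Eif2s3y was at 249 and 109 in wildtype and at 752 and 19 in SOCS3-null cells. Uba1y, dim in wildtype, was at 23.8 and 17.3 and then 146 and 11.9. Both were thus dim on SOCS3-null replicate 2 and not on replicate 1, although Eif2s3y also differed between the wildtype arrays. RNA quality stays open, since its controls disagree. Between the SOCS3-null arrays the actin 3' to 5' log2 ratio differed by 0.0315 (wildtype 0.15) and that of Gapdh by 0.0750 (wildtype 0.0475), which gives no sign of degradation. The 18S probe sets differed by 1.24 to 1.66 (wildtype 0.15 to 0.71). Spike-in controls differed too, such as AFFX-DapX-3_at at 749 and 1432 (wildtype 2099 and 1171), so the 18S gap alone does not show poorer RNA. The discordant genes went both ways, 13 higher in SOCS3-null replicate 1 and 21 in replicate 2. A different share of endoderm cells is argued against by all 30 endoderm genes, called or not, whose median difference was -0.11 (-0.24 to 0.05), the largest 1.44. With the 7208 genes in chromosome order, discordant genes lay within 3 places of another in 4 cases (median of 10000 permutations 0, permutation p = 8.0e-04). Genes outside this set that lie between them were not counted. The same number of genes that differed most between the wildtype arrays gave 1 such case. Different chromosome segments or lines of origin may therefore contribute. The pairs include the family members Rhox6 and Rhox9, which co-regulation of neighbours could also produce, and no label tells whether the arrays came from separate clones.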
